A study of Graphilbum sp. with 6 samples.

How the data were processed

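Total RNA from hyphae of Graphilbum sp., a filamentous ascomycete of the order Ophiostomatales, was sequenced on an Illumina platform, per the labels' protocols. The fungus was cultured on potato dextrose agar at 28 °C for 5 days and the mycelium was washed in phosphate-buffered saline. The nematode group was kept with about 300 pine wilt nematodes (Bursaphelenchus xylophilus) for 24 h. Groups and replicate numbers were taken from the sample titles: 3 control and 3 nematode libraries. The protocol text is the same for all 6 libraries, so the titles alone separate the groups. The series text calls the replicates biological and does not say what made them separate.

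The authors deposited 1 table of TPM (a length-scaled share of transcripts), with 6 library columns, 26694 features and a best-hit description for 13460 of them. Each TPM column summed to 1e+06 over all features, within 1 TPM, whatever organism they came from. The 2 further columns, the authors' group means, equalled the means of the 3 libraries to within 3.33e-07 TPM and were not used. Feature names have the form given by the Trinity de novo assembler, per the file headers and names; the assembler, aligner, quantification tool and their versions are not given in the sources used here. No genome or annotation was used, so features have no coordinates, and gene names are the deposited best-hit descriptions. The descriptions name 526 genera. TPM keeps no depth: the number of reads behind each value is unknown and no counting interval is given. A TPM of exactly 0 is reported as listed at 0, and the Results give no fold against a group at 0. The section on processing gives log2 changes after quantile normalization for some features at 0 in every control.

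Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with a mean-variance trend; statmod 1.5.0 was used for the robust version), on features with at least 1 TPM in at least 3 of the 6 libraries. The contrast was nematode minus control with no covariate, and p-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. A log2 fold change on this scale understates the change of features with low TPM. All p-values given come from limma, by its moderated test for features and by its list test, camera, for lists. An exact two-sided permutation of 3 against 3 libraries cannot go below 0.1. Keyword lists (24) were matched in the descriptions and tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation, where at least 5 members were tested. Members were taken by keyword alone, so a list can hold genes outside its name. The test, its filter, the lists, the naming rule and most alternatives were chosen before the data were examined.

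Features named were the 10 largest rises and the 10 largest falls past the threshold whose libraries did not overlap between groups and whose higher group averaged at least 10 TPM, the 5 features of highest mean TPM past the threshold, and up to 4 members per list with the smallest raw p. Features named outside this rule are said to be so.

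After the data were seen, genera holding the most best hits (94 genera) were assigned by hand to taxonomic groups, and a 2nd fit was added for the 4613 features whose best hit lies in Ophiostomatales (Sporothrix, Grosmannia, Ophiostoma or Esteya). Within this class, each library was divided by the median ratio of its features to their geometric mean over libraries, and the class totals were set to average 1e+06. The same filter, model, lists and naming rule were then applied, and values of this fit are called rescaled TPM. Best hits mark sequence similarity to a database entry, not the organism a transcript came from.

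The scripts were tested on simulated data. For 200 changed Ophiostomatales-hit features, 3 against 3 and diluted by other transcripts, the rescaled fit tested 4531 features. It recovered 81% of 2-fold and 100% of 4-fold changes and called 7 unchanged features. The fit on the undivided TPM, with 4495 features tested, called 3981 unchanged features. For all features (19355 tested), 18% of 2-fold and 90% of 4-fold changes were recovered, with 15 unchanged features among 123 calls. Changed features were drawn only from those above a minimum mean TPM, so recovery at lower TPM was not tested. A list with every member shifted 2-fold was found and 0 of the other lists were called. Smaller list shifts, noise shared between features and a control library that stands apart were not simulated. The simulation of all features and that of the lists held no large set of features found in the nematode libraries alone. Their recovery and false calls therefore do not carry over to the real fit over all features.

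Alternatives were a pseudocount of 0.1 or 5 TPM, no filter or a filter of 5 TPM, rescaling by TMM (trimmed mean of M values, trimming 30% and 5%), quantile normalization, a replicate block, eBayes with robust=TRUE or without a trend, and leaving out each library. Equal class totals, a class defined by at least 1 TPM in every control, left-out libraries with the tested features kept, and whole-word keywords for the signalling list were added after the data were seen.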

Results

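Gene expression was measured by RNA sequencing in hyphae of Graphilbum sp., a fungus of the order Ophiostomatales, which holds wood-colonizing fungi of conifers. The study compared 3 control libraries with 3 libraries from hyphae kept for 24 h with about 300 pine wilt nematodes, Bursaphelenchus xylophilus, which cause pine wilt and feed on fungal hyphae. The question was how the fungus responds to the nematode. The table lists 26694 assembled features in TPM, so the read depth behind each value is unknown. Features with at least 1 TPM numbered 9659, 9255 and 8339 in control replicates 1 to 3 and 22612, 22389 and 22470 in nematode replicates 1 to 3, a mean of 9084 ± 676.3 (SD, n = 3) against 22490 ± 112.9 (SD, n = 3).

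The nematode libraries held a large set of features that the controls lacked. These 13300 features had at least 1 TPM in all 3 nematode libraries and under 1 TPM in every control, and took 53.7%, 39.9% and 40.4% of TPM in nematode replicates 1 to 3 (44.6% ± 7.80, SD, n = 3) against 0.00515% ± 0.00291 (SD, n = 3) of TPM in the controls. The reverse set, present in all controls and in none of the nematode libraries at 1 TPM, had 185 features. Of the treated-only features, 7467 had no best hit and 3991 had a best hit in early-diverging fungi such as chytrids and zygomycetes, which is 91.0% of all features with such a hit. Only 4 had a best hit in Ophiostomatales, the group of the 4613 features that made up 69.3% ± 0.762 (SD, n = 3) of TPM in the controls and 35.5% ± 5.89 (SD, n = 3) in the nematode libraries.

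**Figure D1:**
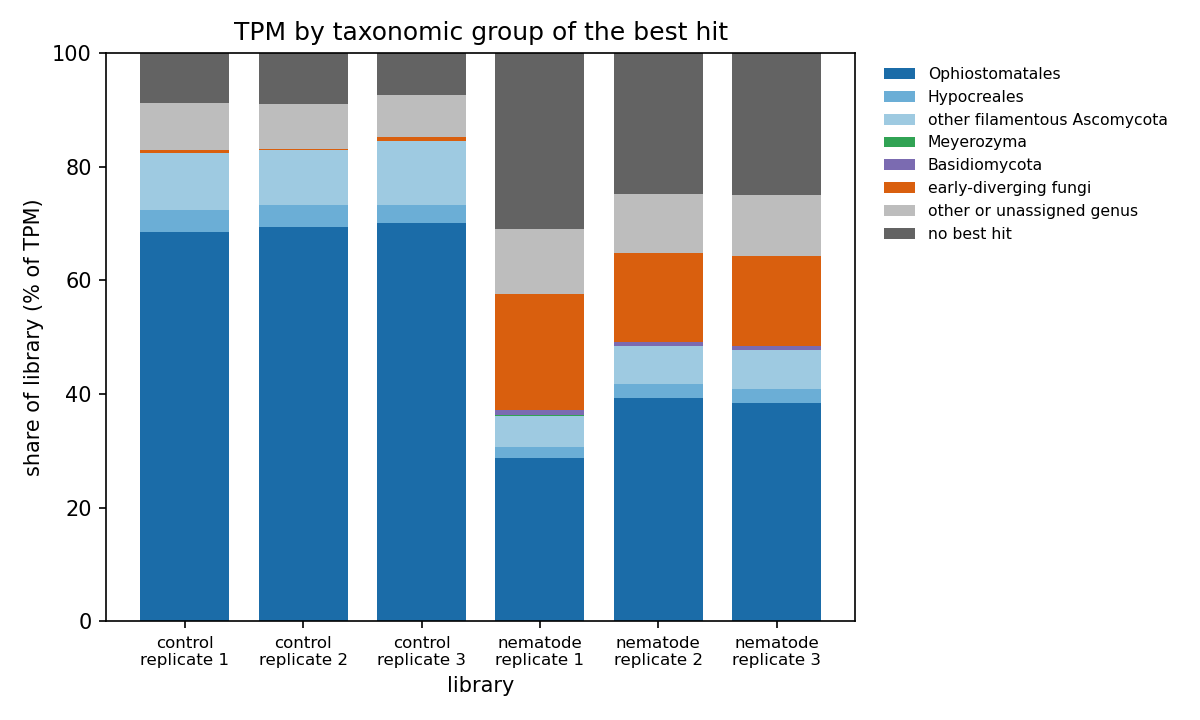
Share of each library's TPM, in percent, by taxonomic group of the best hit, 1 stacked bar per library. Ophiostomatales-hit features held 68.5% to 70.0% of TPM in the 3 controls and 28.7% to 39.4% in the 3 nematode libraries, where early-diverging hits held 15.6% to 20.4%.

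Among the 21817 features tested, 13395 were higher and 5569 lower with nematodes (limma, adjusted p under the threshold of 0.05), and 13367 and 1657 of these changed at least 2-fold. All 13300 treated-only features were among the higher ones, a direction that their definition fixed in advance. The feature with the largest rise, TRINITY_DN6254_c0_g1, had no best hit. It was listed at 1.42, 0 and 0.59 TPM in the controls and at 7318, 6335 and 5423 TPM with nematodes (log2 fold change 11.98 ± 0.33 SE, adjusted p = 1.13e-07). TRINITY_DN6490_c0_g1, described as 60S ribosomal protein L27a with a best hit in Exophiala, had 0.82, 0 and 0 TPM in the controls and 2799, 2412 and 2263 TPM with nematodes (log2 fold change 10.99 ± 0.27 SE, adjusted p = 9.94e-08). Hypothetical proteins with early-diverging hits were of similar abundance: TRINITY_DN7004_c0_g1 (Powellomyces) was listed at 0 in all 3 controls and at 2855, 2399 and 2224 TPM with nematodes. TRINITY_DN5329_c0_g1 (Allomyces) was listed at 0 in all 3 controls and at 2189, 2047 and 1671 TPM.

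Of the 10 largest falls, 7 were listed at 0 in every nematode library, and 6 of these had best hits in Hypocreales, an order of mould fungi outside Ophiostomatales. The 40S ribosomal protein S18-A feature TRINITY_DN20642_c0_g1 had 41.8, 32.1 and 1.90 TPM in control replicates 1 to 3 (adjusted p = 0.00698), and the cold shock protein TRINITY_DN20815_c0_g1 had 43.9, 9.25 and 3.51 TPM (adjusted p = 0.00342). The largest fall, TRINITY_DN22603_c0_g1 with no best hit, had 147.8, 88.2 and 3.21 TPM in the controls (adjusted p = 0.00656). Hypocreales-hit features listed at 0 in every nematode library numbered 539, 425 and 27 at 1 TPM or more in control replicates 1 to 3. Whether they were transcripts of Graphilbum was not tested. Control replicate 3 was lowest for all 7 falls listed at 0 with nematodes. Each had at least 1 TPM in the 3 controls alone and so could not be tested without any 1 of them. With the tested features kept, an omission of nematode replicate 1 gave TRINITY_DN20642_c0_g1 an adjusted p of 0.0538 and TRINITY_DN22603_c0_g1 an adjusted p of 0.0520 (0.0464 and 0.0438 with the filter applied again), whereas TRINITY_DN20815_c0_g1 passed under each of the 6 omissions.

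The most abundant features past the threshold included Ophiostomatales genes of lower TPM with nematodes. Glyceraldehyde-3-phosphate dehydrogenase, a glycolytic enzyme (TRINITY_DN4442_c2_g1), had 25310 ± 16030 TPM (SD, n = 3) in controls and 8869 ± 2521 TPM (SD, n = 3) with nematodes, a log2 fold change of -1.37 ± 0.43 SE (adjusted p = 0.0210). Control replicate 3 had 43760 TPM against 17370 and 14790 in control replicates 1 and 2, and without it the log2 fold change was -0.89 (adjusted p = 0.00731). The cipc-like antibiotic response protein TRINITY_DN12287_c0_g1 had 13230 ± 555.2 TPM (SD, n = 3) against 7235 ± 1216 TPM (SD, n = 3), a log2 fold change of -0.88 ± 0.16 SE (adjusted p = 0.00189). Of 4463 Ophiostomatales-hit features tested, 3515 were lower and 21 higher in TPM as deposited, with a median log2 fold change of -0.82, whereas 4000 of 4102 early-diverging hits were higher, with a median of 3.73. Basidiomycota hits had 135 higher and 1 lower, Hypocreales hits 85 and 169, other filamentous ascomycetes 187 and 398, the yeast Meyerozyma 54 and 0, unassigned genera 1414 and 240, and features with no best hit 7499 and 1241. Without nematode replicate 1, TRINITY_DN4442_c2_g1 had a log2 fold change of -1.24 (adjusted p = 0.129, or 0.114 with the tested features kept). Without nematode replicate 3 it had -1.28 (adjusted p = 0.0464, or 0.0896). TRINITY_DN12287_c0_g1 had -0.76 and -0.90 without nematode replicates 1 and 2 (adjusted p = 0.0781 and 0.0758), and passed both omissions with the tested features kept (adjusted p = 0.00143 and 0.00711).

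**Figure D2:**
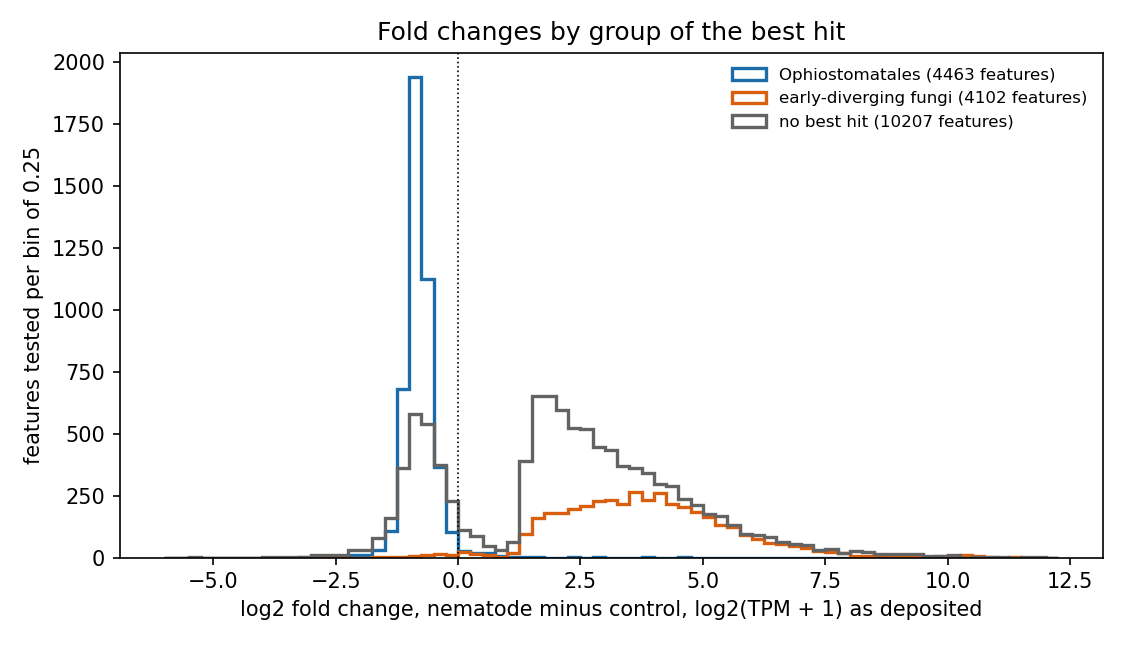
Number of features tested (vertical axis, per bin of 0.25) against the log2 fold change of deposited TPM, nematode minus control, for 3 groups of best hits. Ophiostomatales hits form a single peak around a median of -0.82, early-diverging hits lie mostly above 0 around a median of 3.73, and features without a best hit have 1 peak on each side of 0.

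The balance of rises and falls depended on the scaling. TMM rescaling gave 14002 higher and 320 lower (97.8% higher, against 70.6% as deposited) with a median log2 fold change of 2.23 in place of 2.00, and quantile normalization gave 7991 higher and 10351 lower (43.6% higher) with a median of -0.20. Ophiostomatales hits had 158 higher and 112 lower after TMM (median -0.05) and 5 and 4227 after quantile normalization. Early-diverging hits had 4046 and 0 after TMM and 2884 and 555 after quantile normalization. Hypocreales hits had 90 higher and 31 lower after TMM and 48 and 228 after quantile normalization, and other filamentous ascomycetes 214 and 20 and 105 and 530. Meyerozyma hits had 59 and 0 after TMM and 6 and 9 after quantile normalization, Basidiomycota 138 and 0 and 90 and 38, unassigned genera 1452 and 17 and 969 and 543, and features with no best hit 7845 and 140 and 3884 and 4221. Both scalings ended the call of TRINITY_DN4442_c2_g1 and TRINITY_DN12287_c0_g1, and quantile normalization gave the latter a log2 fold change of 0.12. Leaving out nematode replicate 1, 2 or 3 gave 3113, 4762 and 3665 calls in all, since 0 of the treated-only features then had 1 TPM in 3 libraries and could be tested. With the tested features kept, an alternative chosen after seeing the data, the same omissions gave 17395, 18514 and 17808.

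Ribosome biogenesis had the smallest p of the gene lists in deposited TPM: of its 47 members, 39 were lower, 7 higher and 1 not past, with the same counts adjusted over the list alone (camera adjusted p = 1.32e-08). In cell wall synthesis, 12 of 21 members were lower, 1 higher and 8 not past (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.000122), among them an alpha-mannosyltransferase of protein and wall glycans (TRINITY_DN1970_c0_g1; 64.7 ± 3.67 to 35.2 ± 6.02 TPM, SD, n = 3). Its 20 Ophiostomatales-hit members tested were higher as a list once that class was rescaled (adjusted p = 0.00539; 0.384 with an estimated correlation, and 0.132 without control replicate 3). Conidiation and development had the lowest median log2 fold change, -1.05 against -0.89 in ribosome biogenesis, with 4 lower, 0 higher and 1 not past (adjusted p = 0.00679), among them the conidiophore development protein hyma (TRINITY_DN4113_c1_g3; 121.4 ± 3.71 to 59.0 ± 12.28 TPM, SD, n = 3). After rescaling of the class, 0 of 40 Ophiostomatales-hit members of ribosome biogenesis (median -0.10) and 0 of 4 of conidiation and development (median -0.35) passed. In all, 14 of 22 lists tested were lower relative to the other features, whose median stood near 2.00, and 0 were higher. Of the 21817 features tested, 13300 were treated-only, and all of these were higher, a direction set by their definition. A list with a smaller share of such features can be called lower for that alone, so the calls do not by themselves show a fall of a pathway. In heat shock and chaperones, for example, all 27 higher members were treated-only. None of the 14 passed with an estimated correlation, where their adjusted p ranged from 0.167 to 0.521. Without nematode replicate 1, 2 or 3, 4, 4 and 1 lists were lower, and 14 in each case with the tested features kept.

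The other lower lists mixed opposite members. Ribosomal proteins had 85 higher, 75 lower and 49 not past (adjusted p = 0.00920), heat shock and chaperones 27, 34 and 9 (0.00679), the respiratory chain 24, 34 and 11 (0.00679) and glycolysis and gluconeogenesis 15, 22 and 9 (0.00857). MFS transporters had 50 higher, 52 lower and 26 not past (0.00210), aromatic compound breakdown 25, 34 and 15 (0.00107), plant polysaccharide breakdown 24, 31 and 13 (0.00351) and nitrogen and amino acid uptake 14, 17 and 12 (0.00351). Sterol synthesis had 11, 13 and 11 (0.00920), fatty acid oxidation 18, 23 and 3 (0.0239), and DNA replication and cell cycle 29, 24 and 18 (0.0245). The 36 Ophiostomatales-hit members of the last list were higher once that class was rescaled (adjusted p = 0.000294; 0.384 with an estimated correlation). Counts adjusted over the list alone differed by at most 1. Ribosomal proteins had a median log2 fold change of 0.22 and a mean of 2.06, both above 0, and the other lists of this paragraph had a median below 0 and a mean above 0, such as -0.53 and 1.29 in heat shock and chaperones. After quantile normalization, only MFS transporters, ribosome biogenesis, nitrogen and amino acid uptake and aromatic compound breakdown of the 14 remained lower, joined by cytochrome P450 (adjusted p = 0.00503) and ABC transporters (adjusted p = 0.0256). After TMM, the respiratory chain (adjusted p = 0.0706), fatty acid oxidation (0.0961) and DNA replication and cell cycle (0.423) did not pass.

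All 28 higher antioxidant features were treated-only, for example superoxide dismutase TRINITY_DN22402_c0_g1 with an early-diverging hit, at 0.04 ± 0.0693 TPM (SD, n = 3) in controls and 158.0 ± 28.7 TPM (SD, n = 3) with nematodes (adjusted p = 9.61e-08). Among ribosomal proteins, 74 features were treated-only, 0 of them with an Ophiostomatales hit, such as 40S ribosomal protein S13 (TRINITY_DN4589_c0_g1), which was listed at 0 in all controls and had an early-diverging hit. Of 103 distinct ribosomal protein names (such as S13, with suffixed variants counted apart), 39 had an Ophiostomatales feature in all controls, 59 a treated-only feature, and 19 had both. Since 1 protein can carry more than 1 such name, the overlap of proteins may be larger. The antioxidant list as a whole (28 higher, 18 lower and 1 not past) did not pass (adjusted p = 0.688), nor did cytochrome P450 (21, 10 and 6), ABC transporters (14, 11 and 4), proteases (39, 27 and 8), chitin breakdown (5, 3 and 1), secondary metabolism (7, 1 and 1), the TCA and glyoxylate cycles (17, 15 and 0) or signalling (705, 398 and 104), with an adjusted p of 0.139 to 0.747. Of the 1288 features matched by the signalling list, 992 matched the words containing protein, so its counts do not describe signalling genes alone. The whole-word version of that list, added after the data were seen, had 20 higher and 14 lower of 41 tested. Surface and secreted proteins had 2 higher and 2 lower, too few for a list test. TMM ended the calls of both lower members (TRINITY_DN2129_c0_g1 and TRINITY_DN247_c0_g2), and quantile normalization turned the higher TRINITY_DN4791_c0_g1 to a log2 fold change of -1.95. A list of nematode keywords, such as vitellogenin and cuticle collagen, matched 0 descriptions. Every genus assigned to a group here is fungal, so this cannot tell whether nematode transcripts were present.

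To compare the Ophiostomatales-hit features among themselves, a fit chosen after seeing the data divided each library by the median ratio of that class. After this rescaling, 28 of 4568 features rose and 2 fell (22 and 1 at least 2-fold, and 494 at an unadjusted p under 0.05), and 97.9% had a log2 fold change within 1 of 0. The largest rise was that of a CFEM domain protein, a cysteine-rich domain found in fungal surface and secreted proteins (TRINITY_DN509_c0_g1). It had 6.53 ± 2.38 rescaled TPM (SD, n = 3) in controls and 338.1 ± 37.6 (SD, n = 3) with nematodes, a log2 fold change of 5.54 ± 0.24 SE (adjusted p = 0.000189). An amino acid permease, a membrane importer of amino acids (TRINITY_DN14813_c0_g1), rose from 1.01 ± 0.0725 to 33.7 ± 20.6 (SD, n = 3; log2 fold change 3.96 ± 0.38 SE, adjusted p = 0.00807). A nonribosomal peptide synthetase, a class of enzymes that assemble peptides without ribosomes (TRINITY_DN8287_c0_g1), rose from 2.97 ± 0.425 to 19.7 ± 1.47 (SD, n = 3; log2 fold change 2.38 ± 0.16 SE, adjusted p = 0.00238).

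The hypothetical protein SPI_07499 (TRINITY_DN8092_c0_g1) rose from 1.19 ± 0.396 to 64.9 ± 9.04 rescaled TPM (SD, n = 3; adjusted p = 0.000189). An extracellular serine-rich protein (TRINITY_DN19109_c0_g1) rose from 411.3 ± 83.3 to 1937 ± 451.5 (SD, n = 3; log2 fold change 2.23 ± 0.22 SE, adjusted p = 0.00850), and the hypothetical protein SPI_05293 (TRINITY_DN1849_c1_g2) from 275.7 ± 21.0 to 1027 ± 18.8 (SD, n = 3; adjusted p = 0.000627). The hypothetical protein SPSK_00507 (TRINITY_DN2710_c0_g1) rose by 2.43 on the log2 scale, a DUF1761 domain protein (TRINITY_DN11428_c0_g1) by 2.50 and a purine-cytosine permease (TRINITY_DN20054_c0_g1) by 1.88. The calcium-binding protein NCS-1 (TRINITY_DN2962_c0_g1), of the neuronal calcium sensor family, was listed at 0 in all controls and at 16.3, 7.53 and 11.5 rescaled TPM with nematodes (adjusted p = 0.00574). In the ratio of nematode replicate 1 to replicates 2 and 3, NCS-1 (log2 ratio 0.27) lay nearer to treated-only features (median 0.38) than to Ophiostomatales-hit features (median -0.52). The 2 falls were the hypothetical protein HMPREF1624_08209 (TRINITY_DN5243_c0_g1), from 28.7 ± 3.35 to 12.95 ± 1.99 (SD, n = 3; adjusted p = 0.0382), and a 7alpha-cephem-methoxylase-like protein (TRINITY_DN17305_c0_g1), from 52.1 ± 6.20 to 29.4 ± 0.163 (SD, n = 3; adjusted p = 0.0462). Without control replicate 1 or 2, these 2 falls had an adjusted p of 0.161 to 0.232, and without nematode replicate 1, 2 or 3 of 0.118 to 0.246. Without nematode replicate 1, TRINITY_DN19109_c0_g1, TRINITY_DN11428_c0_g1 and TRINITY_DN20054_c0_g1 had an adjusted p of 0.0857, and the last had 0.0594 and 0.0548 without nematode replicates 2 and 3. NCS-1 could not be tested without a nematode library. With equal class totals, 48 features rose and 0 fell, and the median log2 fold change was 0.11 in place of -0.03.

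**Figure D3:**
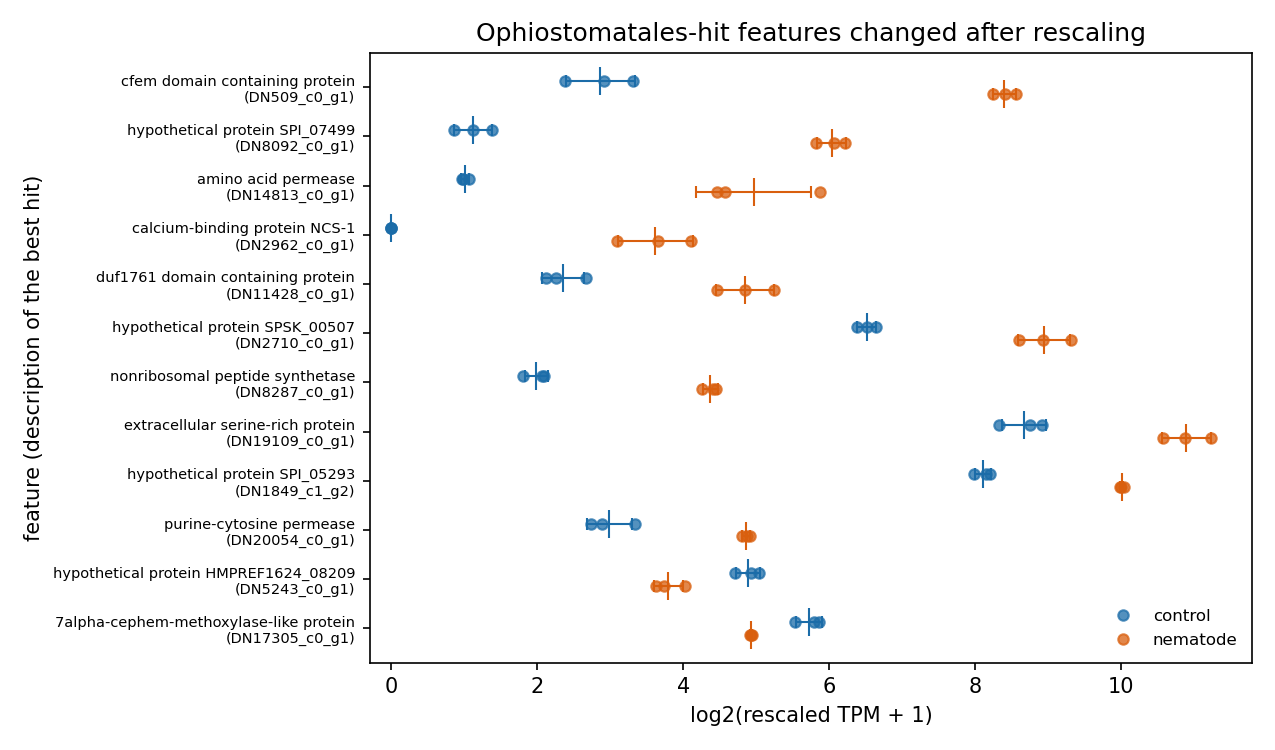
Expression of the 10 Ophiostomatales-hit features with the largest rise and the 2 that fell, as log2(rescaled TPM + 1) on the horizontal axis. Points are libraries (3 per group), the vertical tick is the group mean and the bar is 1 SD. The CFEM domain protein at the top went from 6.53 to 338.1 rescaled TPM, and the groups do not overlap for any of the 12 features, which the naming rule required.

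Enzymes acting on aromatic compounds and 2 cytochromes P450 were among the features that rose. Laccase, a copper oxidase of phenolic compounds (TRINITY_DN415_c0_g1), rose from 15.5 ± 1.31 to 47.5 ± 6.89 rescaled TPM (SD, n = 3; log2 fold change 1.55 ± 0.14 SE, adjusted p = 0.00695). A benzoate 4-monooxygenase cytochrome P450 (TRINITY_DN7888_c0_g1) rose from 10.2 ± 2.27 to 25.9 ± 1.62 (SD, n = 3; adjusted p = 0.0341), and the P450 monooxygenase TRINITY_DN1637_c0_g1 from 71.3 ± 6.13 to 117.2 ± 4.65 (SD, n = 3; adjusted p = 0.0381). In aromatic compound breakdown, 2 of 46 members rose, 0 fell and 44 were not past. Adjusted over the list alone, 3 rose and 1 fell. Of 13 cytochrome P450 members, 2 rose over all features and 2 adjusted over the list alone. Without control replicate 3, aromatic compound breakdown had 5 members higher and 4 lower over all features, and cytochrome P450 had 2 higher and 2 lower. The 4 lower members of the aromatic list were described as taurine or phytanoyl dioxygenases, which the list's keyword dioxygenase matched. The 5 higher were laccase, the benzoate and pentachlorophenol 4-monooxygenases, and 2-nitropropane and xanthine dioxygenases. A subtilisin-like serine protease, an endopeptidase (TRINITY_DN3446_c0_g1), rose from 9.80 ± 0.430 to 28.5 ± 7.63 (SD, n = 3; adjusted p = 0.0381) as the 1 call among 36 proteases. Its replicate log2 ratio of 0.06 also lay nearer to treated-only features than to Ophiostomatales-hit features. Laccase passed under each of the 6 omissions. TRINITY_DN7888_c0_g1 had an adjusted p of 0.129 without control replicate 1 and of 0.177, 0.195 and 0.198 without nematode replicates 1 to 3. TRINITY_DN1637_c0_g1 had 0.1997 and 0.150 without control replicates 1 and 2 and 0.205, 0.195 and 0.213 without nematode replicates 1 to 3. TRINITY_DN3446_c0_g1 had 0.129 and 0.138 without control replicates 1 and 2 and 0.142 and 0.201 without nematode replicates 1 and 3.

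DNA replication and cell cycle genes and cell wall synthesis genes were higher as lists after rescaling, in contrast to the lower calls in deposited TPM, although 0 of their members passed over all features. The 36 replication and cell cycle members had a median log2 fold change of 0.19, and 4 rose adjusted over the list alone (camera adjusted p = 0.000294; adjusted p = 0.384 with an estimated correlation). They included the replicative helicase subunits mcm3 (TRINITY_DN7290_c0_g1; 34.1 ± 1.73 to 55.3 ± 5.07 rescaled TPM, SD, n = 3), minichromosome maintenance protein 2 (TRINITY_DN200_c0_g3; 39.5 ± 0.298 to 56.0 ± 3.36) and mcm6 (TRINITY_DN200_c0_g2; 19.8 ± 0.707 to 28.6 ± 1.80), and the replication regulator sld2 (TRINITY_DN5907_c0_g1; 20.9 ± 1.30 to 32.2 ± 2.12). The 20 cell wall synthesis members had a median of 0.16, and 2 rose adjusted over the list alone (camera adjusted p = 0.00539; adjusted p = 0.384 with an estimated correlation, and 0.132 without control replicate 3). Under equal class totals, TMM and quantile normalization, the adjusted p of replication and cell cycle ranged from 0.000275 to 0.00209 and that of cell wall synthesis from 0.00395 to 0.0143. The 2 cell wall members were the glucan-remodelling beta-glucanosyltransferase gel1 (TRINITY_DN3305_c0_g1; 138.6 ± 36.4 to 246.2 ± 15.6) and a chitin synthase (TRINITY_DN2756_c0_g1; 283.9 ± 36.9 to 473.3 ± 82.3).

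The remaining lists were not past the list threshold after rescaling, with a camera adjusted p of 0.0692 to 0.876. Plant polysaccharide breakdown had 0 of 38 members past over all features and 3 higher adjusted over the list alone, among them endoglucanase 2 (TRINITY_DN1879_c0_g1; 314.5 ± 7.39 to 473.6 ± 23.7, SD, n = 3). The keywords of this list matched glycoside hydrolases of any family, such as families 18 and 55, so not every member need act on plant polysaccharides. Nitrogen and amino acid uptake had 1 of 34 higher, which was the permease above, and secondary metabolism 1 of 6, the peptide synthetase, with a list median of -0.19 and a mean of 0.28. Signalling had 5 of 461 higher; most of this list matched the words containing protein, and its whole-word version had 0 of 19 past. Ribosomal proteins (camera adjusted p = 0.782) were higher after quantile normalization (adjusted p = 0.0385). No member passed, over all features or adjusted over the list alone, among antioxidant genes (15 tested), heat shock and chaperones (35), MFS transporters (57), ABC transporters (14), chitin breakdown (5), sterol synthesis (21), ribosomal proteins (54), ribosome biogenesis (40), respiratory chain (34), TCA and glyoxylate cycles (12), glycolysis and gluconeogenesis (23), fatty acid oxidation (25) or conidiation and development (4). Among 4 surface and secreted proteins, the CFEM protein TRINITY_DN509_c0_g1 passed over all features, and adjusted over the list alone a 2nd CFEM protein did (TRINITY_DN4791_c0_g1; 8.45 ± 2.98 to 26.5 ± 1.43, SD, n = 3). Heat shock protein 30 (TRINITY_DN2618_c0_g2) had 6016 ± 7364 against 663.8 ± 174.0 rescaled TPM (SD, n = 3) and did not pass (adjusted p = 0.421).

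Control replicate 3 stood apart from the other controls in these features. Its Pearson correlation across features was 0.962 and 0.959 with control replicates 1 and 2, which correlated at 0.992 with each other, while nematode libraries correlated at 0.986 to 0.987 among themselves. Control replicates 1 and 2 correlated at 0.972 to 0.98 with the nematode libraries, which is higher than with control replicate 3. Without control replicate 3, 349 features rose and 280 fell (50 and 22 at least 2-fold), including all 28 rises and both falls found with all libraries. Gel1 (TRINITY_DN3305_c0_g1; log2 fold change 1.06 ± 0.08 SE, adjusted p = 0.00159), the chitin synthase TRINITY_DN2756_c0_g1 (0.84 ± 0.14 SE, adjusted p = 0.0149) and mcm3 (TRINITY_DN7290_c0_g1; 0.73 ± 0.10 SE, adjusted p = 0.00990) then rose over all features, where they had an adjusted p of 0.134, 0.1375 and 0.0608 with all libraries. Cell wall synthesis then had 6 members higher and 2 lower over all features, and DNA replication and cell cycle 9 and 2. Of the lists, DNA replication and cell cycle stayed higher (adjusted p = 0.00845), cell wall synthesis did not pass (adjusted p = 0.132), and ribosomal proteins (adjusted p = 9.39e-06) and ribosome biogenesis (adjusted p = 9.35e-05) were lower. With an estimated correlation their adjusted p was 0.691 for replication and 0.767 for the other 3 lists. Each other omission lowered the number of calls, to 14 and 15 without control replicates 1 and 2 and to 7, 15 and 12 without nematode replicates 1, 2 and 3. The 7 features past the threshold under every omission were the CFEM domain protein TRINITY_DN509_c0_g1, SPI_07499, the amino acid permease, SPSK_00507, the nonribosomal peptide synthetase, SPI_05293 and laccase.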

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

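The left-out libraries with the tested features kept, and all alternatives for Ophiostomatales-hit features, were chosen after seeing the data. Over all features, the pseudocount of 5 TPM gave 9709 features changed at least 2-fold (756 lower), and the filter of 5 TPM gave 8048 higher and 9415 changed at least 2-fold (8037 higher). TMM gave 320 lower (127 at least 2-fold) and turned TRINITY_DN4414_c0_g1 to 0.00344, TRINITY_DN2129_c0_g1 to 0.00674 and TRINITY_DN247_c0_g2 to 0.236. Quantile normalization gave 7991 higher and 10351 lower (4801 and 7009 at least 2-fold), 6 lower lists, and TRINITY_DN1299_c0_g1 at 0.103, TRINITY_DN12287_c0_g1 at 0.117, TRINITY_DN16214_c0_g1 at -0.0999, TRINITY_DN17205_c0_g1 at -0.0575, TRINITY_DN18216_c0_g1 at -0.534, TRINITY_DN8088_c0_g3 at -0.0495 and TRINITY_DN4791_c0_g1 at -1.95. The estimated correlation gave 0 lower lists. Leaving out each library gave 3113 to 18766 calls, 70 to 13414 higher, 3043 to 5352 lower, 694 to 15680 at least 2-fold (62 to 13381 higher, 632 to 2494 lower), 0 to 1 higher lists and 1 to 14 lower lists. Without a nematode library, 0 of the 13300 treated-only features passed the filter, which sets the low ends of the higher counts; with the tested features kept, the ranges were 17395 to 18867 calls (lowest without nematode replicate 1), 13378 to 13424 higher (lowest without nematode replicate 3) and 681 to 2403 lower at least 2-fold (lowest without nematode replicate 1). For Ophiostomatales-hit features, the replicate block gave 12 calls, 12 higher and 0 lower, all 12 at least 2-fold, and 11 of these were among the 30. Over all features, the replicate block gave 19246 calls, 18619 of them shared. Replicate numbers did not pair the libraries, with correlations of residuals from -0.434 to 0.148. The pseudocount of 5 TPM gave 0 lower at least 2-fold, robust eBayes 1 lower, no trend 2 lower at least 2-fold, and the estimated correlation 0 higher lists. Equal class totals gave 48 calls, 48 higher and 0 lower (0 at least 2-fold), with TRINITY_DN2609_c0_g1 at 0.000782. Taking all features with at least 1 TPM in every control gave 83 calls, 53 higher and 30 lower (67, 39 and 28 at least 2-fold). Leaving out each library gave 7 to 629 calls, 7 to 349 higher, 0 to 280 lower, 7 to 72 at least 2-fold (7 to 50 higher, 0 to 22 lower), 1 to 2 higher lists and 0 to 2 lower lists. Over these omissions, 5 features not past the threshold with all libraries changed sign: TRINITY_DN2053_c0_g1 (-0.344 to 0.0262), TRINITY_DN60_c0_g1 (-0.268 to 0.0237), TRINITY_DN2129_c0_g1 (-0.0328 to 0.144), TRINITY_DN265_c0_g2 (-1.49 to 0.00638) and TRINITY_DN2609_c0_g1 (-0.217 to 0.00539). Except for the filter, the cause was not tested. TPM keeps no depth, so what depth limits is unknown.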

Other observations

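The tests of treated-only features, of the fall in deposited TPM and of the splits over all features were chosen after the result was seen, and the features named in the next 2 paragraphs were chosen after their values were seen.

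Among Ophiostomatales-hit features outside the naming rule, a glucose-methanol-choline oxidoreductase (TRINITY_DN807_c2_g1) rose from 17.2 ± 1.09 to 45.7 ± 9.30 rescaled TPM (SD, n = 3; adjusted p = 0.0208). A beta-glucan-binding protein (TRINITY_DN20263_c0_g1) rose from 21.9 ± 3.44 to 76.4 ± 24.9 (SD, n = 3; adjusted p = 0.0368) and the large subunit of DNA primase (TRINITY_DN1997_c0_g2) from 48.9 ± 3.47 to 79.6 ± 2.14 (SD, n = 3; adjusted p = 0.0368). Without control replicates 1 and 2 and nematode replicates 1, 2 and 3, their adjusted p was 0.0832, 0.0943, 0.0779, 0.0497 and 0.117 for the oxidoreductase, 0.121, 0.0995, 0.1865, 0.0535 and 0.0865 for the beta-glucan-binding protein, and 0.202, 0.120, 0.198, 0.195 and 0.205 for the primase. Features for which control replicate 3 lay on the other side of the nematode libraries include 4 given here as examples, none past the threshold with all 6 libraries. Spore germination protein TRINITY_DN265_c0_g2 had 133.9, 219.2 and 26.4 rescaled TPM in control replicates 1 to 3 and 50.8, 48.2 and 89.1 with nematodes (log2 fold change -0.61, adjusted p = 0.810; -1.49, adjusted p = 0.0260 without control replicate 3). The sterol regulator sre1 TRINITY_DN174_c0_g2 had 24.7, 19.0 and 57.2 against 42.0, 44.3 and 35.9 (log2 fold change 0.42, adjusted p = 0.740; 0.88, adjusted p = 0.0152 without it). Sporulation-specific protein 5 TRINITY_DN517_c0_g1 (-0.47) and bZIP-1 TRINITY_DN1251_c0_g1 (-0.76) had an adjusted p of 0.594 with all 6 libraries, and of 0.0116 (-0.77) and 0.00232 (-1.29) without it.

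The controls held transcripts with best hits outside Ophiostomatales that were unequal among replicates. Features listed at 0 in every nematode library numbered 1414, of which 1031, 844 and 163 had at least 1 TPM in control replicates 1, 2 and 3, and 539, 425 and 27 of these had Hypocreales hits against 13, 9 and 9 with Ophiostomatales hits. Features with hits in the yeast Meyerozyma summed to 76.6, 0 and 0 TPM in the controls and to 568.8, 335.5 and 928.6 TPM in the nematode libraries.

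Treated-only features may be transcripts of another organism present in the nematode libraries, such as the added nematodes. Of these features, 85.83% were higher in nematode replicate 1 than in the mean of replicates 2 and 3 (median log2 ratio 0.38), against 1.46% of Ophiostomatales-hit features (median -0.52). Genes of any source with a larger share of TPM in replicate 1 would give the same, so this ratio alone leaves another organism neither supported nor excluded. Of the treated-only features with a hit in an assigned genus, 0.09031% (4 of 4429) had an Ophiostomatales hit, which argues against fungal genes switched on by the nematodes as the source of those with a hit in another assigned group. The 4 exceptions include NCS-1 and the amino acid permease TRINITY_DN14813_c0_g1. Of 74 treated-only ribosomal protein features, 0 had an Ophiostomatales hit. For 19 ribosomal protein names, a treated-only feature stood beside an Ophiostomatales feature present in all controls. For those names, this also argues against fungal genes switched on by the nematodes. The source of the treated-only features otherwise stays open, since every genus assigned to a group here is fungal and no nematode sequence was at hand. With such best hits, the 0 matches of the nematode keywords cannot decide it.

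The lower deposited TPM of Ophiostomatales-hit features may follow from the fixed TPM total, which they share with features not found in the controls. The median log2 change was -1.14, -0.60 and -0.73 in nematode replicates 1, 2 and 3, and the share of TPM left by those features predicted -1.13, -0.75 and -0.76, a largest gap of 0.1465. A biological fall of most of these genes by the same amount was not tested, since TPM holds no absolute amount of RNA. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many calls over all features, 18964 against 0 in the highest other split, and 10 splits are too few for a share under 0.05.

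For the rises after rescaling, reads of another organism counted under Ophiostomatales-hit features and control replicate 3 were weighed. Only 2 of the 28 risen features, NCS-1 and the subtilisin-like serine protease, had a replicate ratio nearer to treated-only features, which argues against reads from the source of the treated-only features for the other 26. All 28 passed without control replicate 3, but that omission lowered the median SE from 0.156 to 0.109 and gave 629 calls. Features called with all 6 libraries could hardly lose their call there, so this cannot decide whether that library was their source. A response of the fungus to the nematodes stays open for the 26 as an untested explanation, and 9 of them passed in 1 alone of the 6 fits with a library left out, the fit without control replicate 3. Of the 10 splits, 1 (the real one) gave as many calls, 30 against 2 in the highest other split, and 10 splits are too few for a share under 0.05.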
